A study of Mus musculus with 62 samples.

How the data were processed

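The starting values were the non-normalized bead intensities of the series, with 1 value and 1 detection p-value for each probe and array. Per the file headers, each of the 62 samples has a column of detection p-values beside it. The intensities were deposited with no normalization between arrays and no background subtracted, as the values show: all are positive and the array medians differ. The submitters' notes name GenomeStudio 2011 and no role for it. Per the labels' protocols, RNA was extracted with a Qiagen kit, checked by NanoDrop and Bioanalyser, and copied to biotin-labelled cRNA with an Ambion kit. A second set of intensities in the deposited series matrix had been background subtracted and quantile normalized across the 62 arrays, as its values show, by a method not given in the sources used here, and served as an alternative. No genome build was needed.

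Of 25697 probes, 23978 had 1 gene symbol in the platform's annotation and 1719 had no listed symbol. Entrez IDs of 23962 named probes were among the RefSeq genes, which changed 0 symbols. In limma 3.58.1 under R 4.3.3, neqc corrected the background by the normexp model from the detection p-values, added an offset of 16, normalized by quantiles and took log2. Probes with a detection p under 0.01 on at least 4 arrays were kept, 15239 in all, and the probe with the highest mean stood for each of 10316 genes.

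A model with a mean for each of the 6 groups was fitted with lmFit and eBayes, and the 3 comparisons of parental cells used the 12 parental arrays alone. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. Interaction contrasts tested whether the tumor against parental change differed between lineages. A gene with a detection p under 0.01 on no array of a group was set there to the lowest detected value of each array, or to its own value where that was higher, and the fold is then a lower bound. Tumor distances over parental distances are ratios of root mean square log2 differences over all genes, each squared difference less its squared standard error. The spread of tumors around their group mean was compared by a 2-sided permutation test with 100000 resamples.

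The 30 gene lists, the rule for named genes and the comparisons were fixed before the data were examined. Lists covered hepatocyte function (plasma proteins, urea cycle and amino acid catabolism, xenobiotic and bile acid metabolism, gluconeogenesis and fatty acid oxidation, transcription factors), fetal liver, cholangiocyte and progenitor genes, epithelial junction and mesenchymal transition. Others covered mitosis, DNA replication, MAPK output, p53 targets, MYC and ribosome biogenesis, WNT targets, Notch, YAP targets, hypoxia and glycolysis, cholesterol synthesis, interferon response and antigen presentation. The rest were markers of endothelial cells, macrophages, lymphocytes, granulocytes, fibroblasts and stellate cells, skeletal muscle, adipocytes, erythroid cells and keratinocytes. camera tested each list with a preset correlation between genes of 0.01, adjusted over the 30 lists of a comparison, and an estimated correlation was the alternative. Named genes were the 8 largest rises and 8 largest falls of a main comparison, 5 and 5 of the others, 8 per direction of those shared by all lineages, and up to 4 members of each list described. Symbols of clones and predicted genes were passed over. Of 20 genes named in advance, Epcam, Mki67, H19, Hras, Prom1 and Trp53 had no probe past the filter with that symbol.

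Array batches were inferred after the data were seen from 6880 probes with a detection p under 0.05 on at most 2 arrays, as log2 intensities less the array median and the probe mean. Clustering by 3 linkages gave the same 6 batches, with a median correlation of 0.108 within and -0.0617 between batches. Alternatives that use these batches, that leave out pairs of HB parental samples, 10 AH tumors by their numbers or HB tumors 3 and 8, or that add the plasma protein level were added after that. A value without a test counted as moved when it changed by more than its jackknife standard error over samples, and a count when it changed by more than 1.5-fold. statmod 1.5.0 and data.table (version 1.17.8) were also used.

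The fit was tested on simulated arrays of 10316 genes, each at its overall mean with normal noise of its pooled spread within groups. In each comparison 50 genes per fold were changed in 1 group, so the test leaves out spreads that differ between groups. For HPC tumors against parental cells, 44% of 2-fold and 92% of 4-fold changes were called. For HPC against AH parental cells the shares were 12% at 2-fold, 78% at 4-fold and 98% at 8-fold, and between 1 and 7 unchanged genes were called in each of the 12 comparisons.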

Results

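The series compares mouse liver tumors that grew from 3 kinds of transformed liver cell with the parental cells of each kind. The cells of origin were hepatic progenitor cells (HPC), fetal hepatoblasts (HB) and adult hepatocytes (AH). Bead arrays were read for 10 HPC tumors, 20 HB tumors, 20 AH tumors and 4 parental samples of each kind, 62 arrays in all. The labels do not say that samples of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Between 9021 and 12524 probes were detected per array, and the number of arrays limits the precision. The arrays fell into 6 batches, inferred from probes that were almost never detected. Batch 1 held the HPC tumors, AH tumors 7 to 20 and the HPC parental cells, batch 2 HB tumors 1 to 10, and batch 3 HB tumors 11 to 20 and AH tumors 1 to 6. Batches 4 and 5 held HB parental samples 1 and 2, and 3 and 4, and batch 6 the AH parental cells. Values in brackets after a gene are log2 differences ± SE from limma, and a gene was called at an adjusted p under 0.05 with a change of at least 2-fold. Where a gene was not detected on any array of a group, the fold is given as a lower bound. Gene lists were compared with all other genes by camera, and their medians are log2 differences, given also with undetected members at their bounds where that moved them.

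The tumors of the 3 origins resembled one another more than any of them resembled its own parental cells. Across 10316 genes, the root mean square log2 difference was 0.571 between HPC and AH tumors, 0.747 between HPC and HB tumors and 0.499 between HB and AH tumors. Tumors lay 1.34 from their parental cells for HPC and 1.72 for AH, and HB tumors lay 1.53 and 1.30 from HB parental samples 1 and 2, and 3 and 4. The mean of these unlike pairs lay 0.954 from HB tumors after the squared standard error was taken off. That error takes in the gap between the pairs, so the value is too low as a distance to their mean. The median Pearson r across genes was 0.923 between HPC and AH tumor arrays and 0.648 between HPC and AH parental arrays. Without background correction the counts of called genes of the 12 comparisons of groups and changes were lower by more than 1.5-fold, from 221 between HB and AH tumors to 2992 for the difference between the HPC and AH changes. The first 2 principal components carried 29.2% and 15.4% of the variance.

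**Figure D1:**
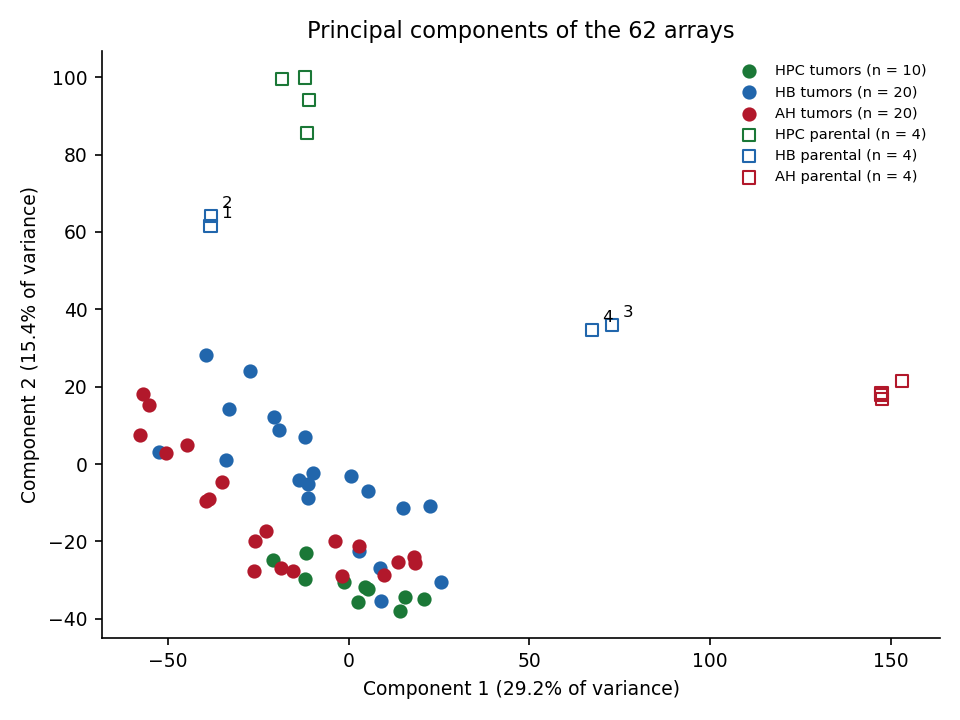
Each point is an array, placed by its first 2 principal components of log2 expression, with filled circles for tumors and open squares for parental cells. The 50 tumors form a single cloud apart from the 12 parental arrays, and HB parental samples 1 and 2 lie apart from samples 3 and 4 (numbers beside the squares).

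**Figure D2:**
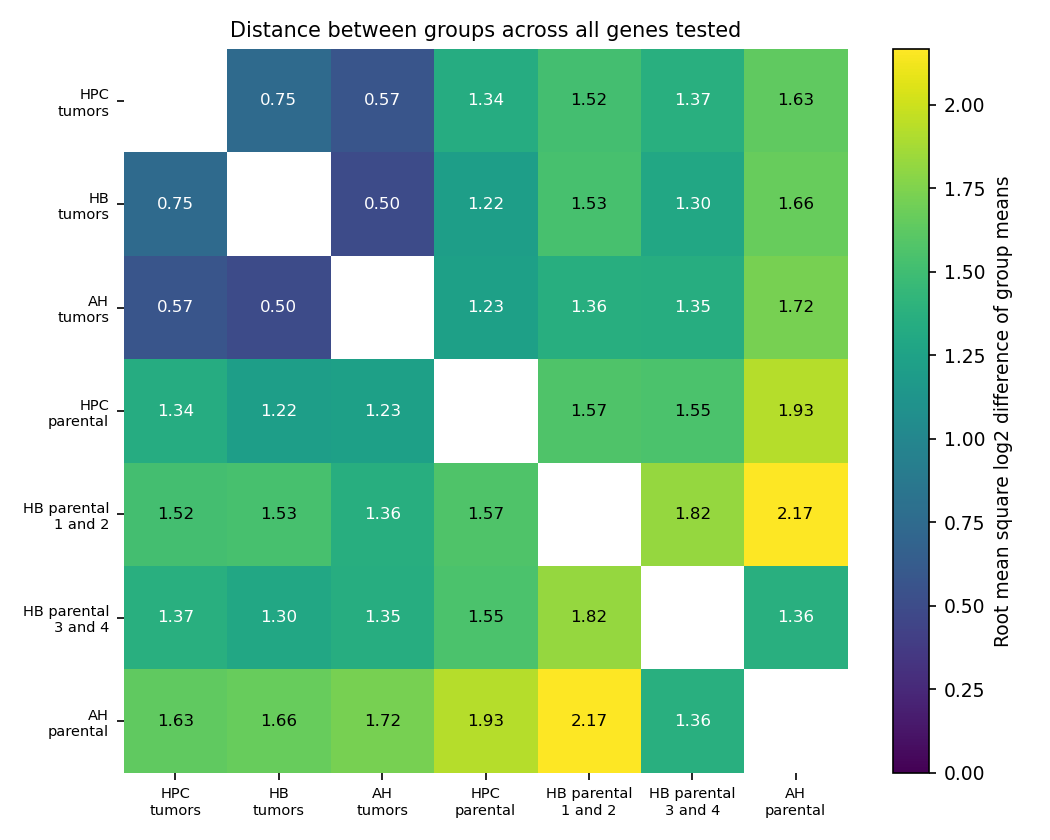
Each cell gives the root mean square log2 difference between the means of 2 groups across all genes tested, with HB parental cells shown as 2 pairs of samples. Distances among tumors run from 0.499 to 0.747, below every distance that involves parental cells.

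The 4 HB parental samples were not alike. Samples 3 and 4 held high levels of Afp, the fetal liver albumin-like protein (13.99 and 13.86, log2), of the adhesion gene Cdh1 and of Hnf4a, a master regulator of hepatocyte genes. In samples 1 and 2 Afp was at 6.50 and 6.60, and the intermediate filament gene Vim was at 13.57 and 14.13, against 8.76 and 8.07 in samples 3 and 4. All 4 samples shared high Igf2, a fetal growth factor, at 13.34, 13.21, 14.67 and 14.66. Pearson r across genes was 0.955 between samples 1 and 2, 0.974 between samples 3 and 4 and at most 0.675 between the pairs. The pairs also fell in separate array batches, which can add to the difference of a single gene, and the comparison between them was added after the data were seen. In limma, 3521 genes were called between the pairs. Plasma protein genes of hepatocytes were higher in samples 3 and 4 for 25 of 26 (25 adjusted over the list alone, median 8.25, 7.49 with bounds, adjusted p = 5.6e-21, or 0.076 with an estimated correlation). Markers of red cell precursors were also higher there, with Hba-a1 at 13.79 and 13.53 against 4.43 and 4.51, for 7 of 7 (7 adjusted over the list alone, median 4.07, 3.25 with bounds, adjusted p = 3.3e-06, and 0.00727 with an estimated correlation). Granulocyte markers were higher for 10 of 12 (10 adjusted over the list alone, median 5.75, 5.00 with bounds, adjusted p = 5.9e-06, or 0.151 with an estimated correlation). Genes of mesenchymal transition were lower in samples 3 and 4 for 19 of 22 (20 adjusted over the list alone, median -4.47, -3.84 with bounds, adjusted p = 7.9e-13, and 0.0314 with an estimated correlation), and fibroblast and stellate cell markers for 16 of 21 (16 adjusted over the list alone, median -4.61, adjusted p = 2.3e-09, or 0.076 with an estimated correlation). Every result that uses HB parental cells is an average over these unlike pairs.

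**Figure D3:**
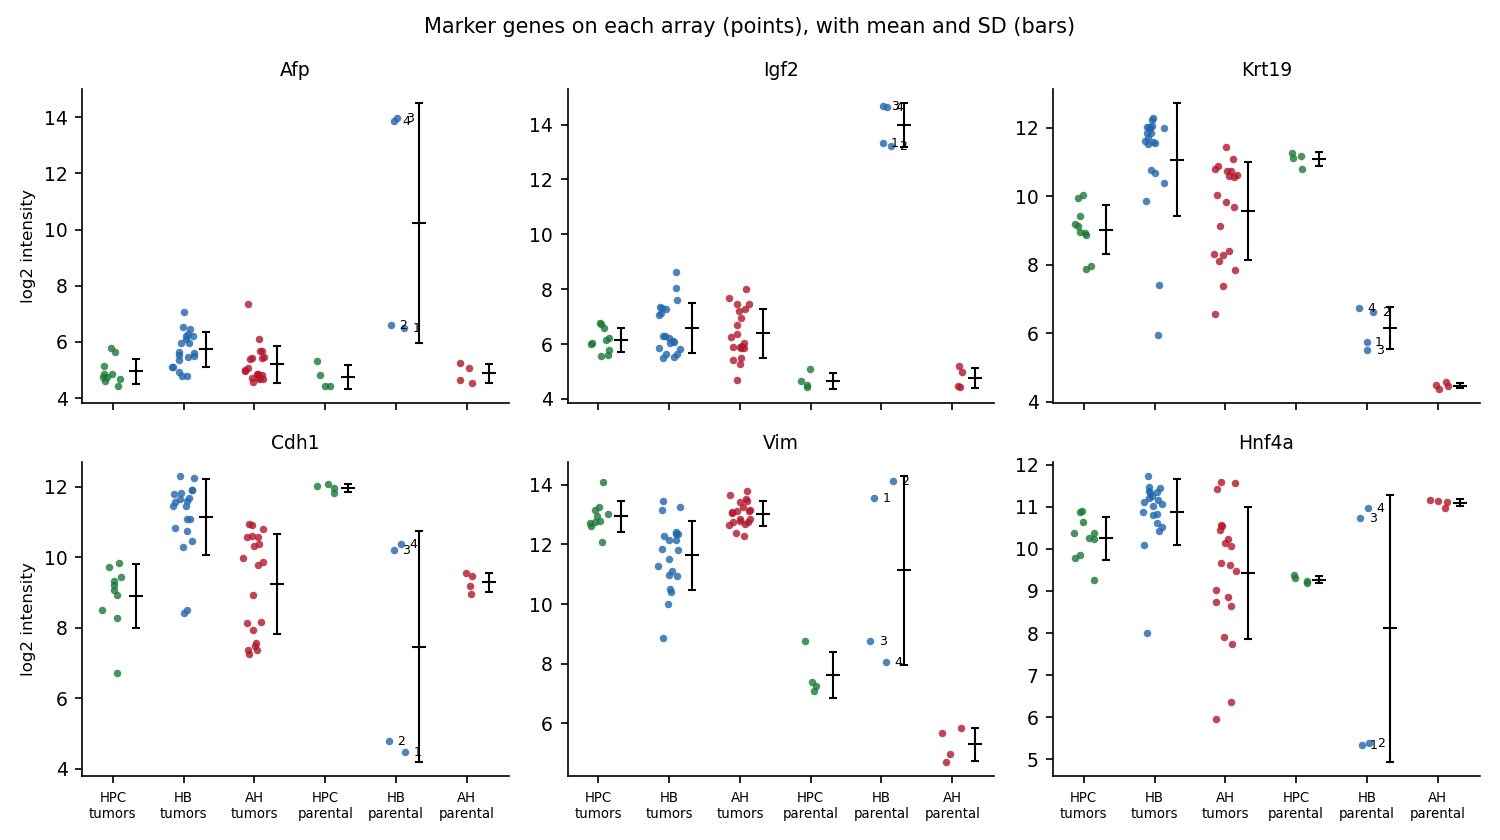
Points show log2 intensity of 6 marker genes on each array by group, with the group mean and SD beside them and HB parental samples numbered. Afp reaches 13.99 only in HB parental samples 3 and 4, while Vim is near 13.57 in HB parental samples 1 and 2 and low in the other parental arrays.

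HPC parental cells and adult hepatocytes carried largely different programs. Adult hepatocytes expressed enzymes of ammonia disposal, drug metabolism and glucose production, and progenitor cells keratins, claudins and other bile duct genes. Among the highest in HPC against AH parental cells were Scara3 (at least 239-fold higher), Sftpd (at least 208-fold higher) and Cldn4 (at least 214-fold higher). Among the lowest were Mup2 (at least 639-fold lower), Cyp2e1 (-9.35 ± 0.99) and Car3 (at least 331-fold lower), products of mature liver. The bile duct keratins Krt19 and Krt7 were at least 26.9-fold higher and at least 53.0-fold higher, and the progenitor regulator Sox9 differed by 4.20 ± 0.40. The cholangiocyte and progenitor list was higher for 15 of 19 (15 adjusted over the list alone, median 4.89, 4.47 with bounds, adjusted p = 2.6e-08, and 0.0367 with an estimated correlation). The urea cycle and amino acid catabolism list was lower for 22 of 22 (22 adjusted over the list alone, median -5.32, -4.98 with bounds, adjusted p = 9.8e-10, or 0.417 with an estimated correlation). Xenobiotic and bile acid metabolism was lower for 20 of 23 (20 adjusted over the list alone, median -6.48, -6.26 with bounds, adjusted p = 9.8e-10, or 0.417 with an estimated correlation). Gluconeogenesis and fatty acid oxidation genes were lower for 12 of 18 (12 adjusted over the list alone, median -3.90, -3.76 with bounds, adjusted p = 9.9e-06, or 0.567 with an estimated correlation). Plasma protein genes were lower for 14 of 26 (14 adjusted over the list alone, median -4.55, adjusted p = 1.9e-04, or 0.671 with an estimated correlation). The member Ambp stood at 14.54 against 14.67 (log2). Epithelial junction genes were higher for 12 of 24 (12 adjusted over the list alone, median 2.62, 2.31 with bounds, adjusted p = 5.0e-04, or 0.567 with an estimated correlation). Mitosis genes such as Kif23 (at least 5.97-fold higher) were higher for 14 of 17 (14 adjusted over the list alone, median 1.88, 1.68 with bounds, adjusted p = 5.3e-05, or 0.417 with an estimated correlation). In limma 4041 genes were called, 2380 higher and 1661 lower. The parental groups shared no array batch, so batch and group cannot be told apart, and with batch as a random block (chosen after the data were seen) 1238 genes were called. With median centring the split was 1682 higher and 2146 lower.

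Against hepatoblasts, HPC parental cells lacked the fetal program. Igf2 (at least 410.0-fold lower), Dlk1 (at least 171-fold lower) and Igf2bp3 (at least 37.4-fold lower), all genes of fetal growth, were lower in HPC cells. The fetal liver list was lower for 12 of 13 (12 adjusted over the list alone, median -4.68, -3.86 with bounds, adjusted p = 9.3e-11, or 0.073 with an estimated correlation). Afp differed by -5.48 ± 1.56, a call lost without HPC parental sample 1 or 3 (-5.37 each) and without background correction. HPC cells were higher in bile duct and epithelial genes, including Krt19 (4.93 ± 0.26) and Cdh1 (4.51 ± 1.20). The cholangiocyte and progenitor list was higher for 16 of 19 (16 adjusted over the list alone, median 4.97, 4.69 with bounds, adjusted p = 2.3e-12, and 0.00809 with an estimated correlation). The epithelial junction list was higher for 19 of 24 (20 adjusted over the list alone, median 3.65, 3.30 with bounds, adjusted p = 9.3e-11, or 0.221 with an estimated correlation). Cd74, the invariant chain of class II antigen presentation, was also higher (8.88 ± 0.35). The antigen presentation list was higher for 14 of 17 (16 adjusted over the list alone, median 2.90, 2.33 with bounds, adjusted p = 2.3e-12, or 0.0536 with an estimated correlation). Mesenchymal genes such as Zeb1 (-2.18 ± 0.47) were lower for 9 of 22 (12 adjusted over the list alone, median -2.52, -2.18 with bounds, adjusted p = 5.9e-05, or 0.584 with an estimated correlation). That difference was lost without HB samples 1 and 2 (median -0.38, adjusted p = 0.316). Cholesterol synthesis genes were lower for 9 of 15 (9 adjusted over the list alone, median -1.43, adjusted p = 1.7e-05, or 0.221 with an estimated correlation). In limma 2142 genes were called, 1380 higher and 762 lower. Without samples 1 and 2 the count was 3558, without samples 3 and 4 it was 3522, and with array batch as a random block it was 368 (303 higher and 65 lower), without Afp, Cdh1 and Zeb1. With median centring it was 784 higher and 1616 lower. Hnf4a differed by 1.16 ± 1.16 (not called) over all samples and by -1.58 without samples 1 and 2.

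Hepatoblasts differed from adult hepatocytes by fetal growth and cell division genes on one side and mature metabolism on the other. Igf2 (at least 198-fold higher), Dlk1 (at least 82.4-fold higher), Afp (at least 14.9-fold higher) and Gpc3, an oncofetal surface protein (at least 15.2-fold higher), were among the fetal genes that were higher, Afp not being called without background correction. The list was higher for 12 of 13 (12 adjusted over the list alone, median 5.36, 3.89 with bounds, adjusted p = 5.5e-09, or 0.141 with an estimated correlation). Mitosis genes, among them Top2a (at least 8.14-fold higher) and Prc1 (at least 18.9-fold higher), were higher for 15 of 17 (15 adjusted over the list alone, median 3.53, 2.50 with bounds, adjusted p = 6.1e-11, or 0.15 with an estimated correlation). DNA replication genes such as Mcm5 (3.34 ± 0.33) were higher for 20 of 26 (20 adjusted over the list alone, median 1.83, 1.15 with bounds, adjusted p = 5.1e-08, or 0.208 with an estimated correlation). Adult liver products were lower, with Mup2 (at least 501-fold lower), Mug1 (at least 380.0-fold lower) and Orm1 (-9.15 ± 0.55). Xenobiotic and bile acid metabolism was lower for 19 of 23 (22 adjusted over the list alone, median -5.13, adjusted p = 4.2e-11, or 0.208 with an estimated correlation). Urea cycle and amino acid catabolism was lower for 20 of 22 (20 adjusted over the list alone, median -4.15, adjusted p = 7.3e-09, or 0.399 with an estimated correlation). Mesenchymal genes such as Vim (at least 27.6-fold higher) and Sparc (4.76 ± 1.12) were higher for 13 of 22 (16 adjusted over the list alone, median 2.77, 1.85 with bounds, adjusted p = 3.4e-04, or 0.529 with an estimated correlation), genes that stood high in HB samples 1 and 2. Antigen presentation genes were lower for 9 of 17 (9 adjusted over the list alone, median -1.26, -0.94 with bounds, adjusted p = 9.6e-06, or 0.164 with an estimated correlation). In limma 2792 genes were called, 1520 higher and 1272 lower. The count was 4549 without HB samples 3 and 4, and 664 with array batch as a random block, without Afp, Vim and Sparc. Cdh1 differed by -1.83 ± 1.20 and Alb by -0.95 ± 0.86 (neither called), but by 1.00 and 1.07 without samples 1 and 2.

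**Figure D4:**
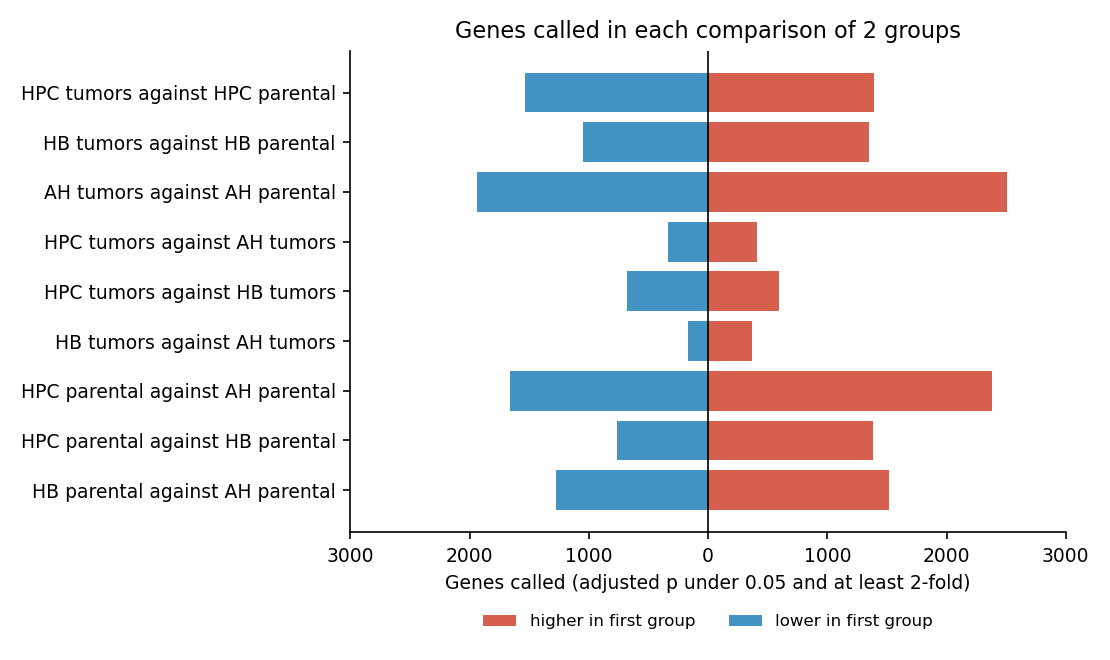
Bars give the number of genes called by limma in each comparison of 2 groups, to the right where higher in the first group and to the left where lower. Tumor against parental comparisons called 2401 to 4446 genes and comparisons between tumors 541 to 1277.

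HPC tumors had lost much of the bile duct character of their parental cells and carried hepatocyte, stromal and cell division transcripts instead. Genes of mature liver were among the largest rises, with Mup2 (at least 422-fold higher), Cyp2e1 (8.18 ± 1.20), Orm1 (7.21 ± 0.83) and Serpina3n (7.80 ± 0.64). The smooth muscle actin gene Acta2 (7.28 ± 0.70) and the hemoglobin gene Hba-a1 (at least 222-fold higher) rose with them. Falling genes included the claudin Cldn4 (-7.72 ± 0.79), the integrin Itgb6 (-7.34 ± 0.52), the trefoil factor Tff2 (-7.14 ± 1.07) and the early response genes Fosb (-7.52 ± 0.45), Fos (-6.81 ± 0.49) and Atf3 (-6.75 ± 0.51). The keratins Krt19 and Krt7 fell by 2.06 and 4.08 on the log2 scale and Cdh1 by 3.06, the Krt19 call being lost without HPC parental sample 2 (-2.01). The mesenchymal gene Vim (5.31 ± 0.61) and the cell cycle inhibitor Cdkn2a (5.81 ± 0.79) rose. In limma 2925 genes were called, 1391 higher and 1534 lower, all 14 arrays lying in batch 1. With median centring the split was 767 higher and 1870 lower.

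Among gene lists, the cholangiocyte and progenitor list fell in HPC tumors for 15 of 19 (15 adjusted over the list alone, median -3.22, -2.58 with bounds, adjusted p = 5.1e-09, or 0.0737 with an estimated correlation). The epithelial junction list fell for 17 of 24 (18 adjusted over the list alone, median -2.64, adjusted p = 3.5e-07, or 0.389 with an estimated correlation). YAP targets such as Ccn1 (-5.13 ± 0.31) fell for 9 of 12 (10 adjusted over the list alone, median -1.94, adjusted p = 1.4e-05, or 0.0737 with an estimated correlation). Axl, a receptor on both the YAP and the mesenchymal lists, rose (4.63 ± 0.47). Plasma protein genes, among them Apoa1 (5.92 ± 0.88) and Apoc3 (6.22 ± 0.95), rose for 21 of 26 (21 adjusted over the list alone, median 4.03, adjusted p = 1.1e-06, or 0.496 with an estimated correlation). Xenobiotic and bile acid genes rose for 16 of 23 (16 adjusted over the list alone, median 3.03, 3.02 with bounds, adjusted p = 9.8e-05, or 0.518 with an estimated correlation). Urea cycle and amino acid genes such as Arg1 (4.94 ± 0.82) rose for 11 of 22 (13 adjusted over the list alone, median 2.06, adjusted p = 5.1e-04, or 0.559 with an estimated correlation). Mitosis genes, Aurka (2.47 ± 0.22) and Top2a (2.62 ± 0.25) among them, rose for 12 of 17 (12 adjusted over the list alone, median 1.82, adjusted p = 1.6e-09, or 0.1 with an estimated correlation). DNA replication genes rose for 20 of 26 (20 adjusted over the list alone, median 1.45, adjusted p = 1.6e-09, or 0.182 with an estimated correlation). Hypoxia and glycolysis genes such as Pkm (3.42 ± 0.40) rose for 10 of 23 (10 adjusted over the list alone, median 0.91, adjusted p = 6.7e-05, or 0.389 with an estimated correlation). Interferon response genes such as Ifit3 (4.18 ± 0.70) rose for 10 of 17 (11 adjusted over the list alone, median 1.74, adjusted p = 1.7e-04, or 0.465 with an estimated correlation).

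Markers of other cell types moved with these changes. Fibroblast and stellate cell markers, including the collagen Col5a1 (5.91 ± 0.57) and the stellate cell globin Cygb (5.46 ± 0.32), rose in HPC tumors for 19 of 21 (19 adjusted over the list alone, median 3.27, adjusted p = 5.1e-09, or 0.196 with an estimated correlation). The pericyte gene Rgs5 fell (-4.23 ± 0.33). Mesenchymal transition genes rose for 16 of 22 (16 adjusted over the list alone, median 2.62, adjusted p = 2.1e-06, or 0.389 with an estimated correlation). Macrophage markers such as C1qa (4.44 ± 0.45) and Adgre1 (3.58 ± 0.44) rose for 11 of 17 (11 adjusted over the list alone, median 1.79, adjusted p = 6.8e-04, or 0.465 with an estimated correlation). Endothelial markers such as Flt1 (4.62 ± 0.46) rose for 10 of 18 (11 adjusted over the list alone, median 1.47, adjusted p = 5.8e-04, or 0.438 with an estimated correlation). Erythroid markers rose for 4 of 7 (4 adjusted over the list alone, median 2.28, 1.63 with bounds, adjusted p = 0.00437, or 0.389 with an estimated correlation).

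HB tumors lost part of the fetal program of hepatoblasts, and most gained bile duct and epithelial transcripts. Igf2 fell most (-7.40 ± 0.43), with Dlk1 (-4.88 ± 0.74), Grb10 (-5.01 ± 0.22), Cdkn1c (-4.60 ± 0.47) and Afp (-4.51 ± 0.61). Igf2bp3 still averaged 9.99 (log2). Rising genes included the adult plasma proteins Mug1 (at least 116-fold higher), Orm1 (8.04 ± 0.77) and Mup2 (at least 95.9-fold higher), the epithelial secreted protein Wfdc2 (7.21 ± 0.57), the trefoil factor Tff1 (at least 97.5-fold higher) and the growth factors of the prolactin family Prl2c3 (6.74 ± 0.62) and Prl2c4 (6.71 ± 0.63). The keratins Krt19 (4.90 ± 0.70) and Krt7 (5.51 ± 0.99) and Cdh1 (3.68 ± 0.71) rose. In limma 2401 genes were called, 1352 higher and 1049 lower. Against samples 1 and 2 alone, then samples 3 and 4 alone, Igf2 differed by -6.71 ± 0.57 and -8.10 ± 0.57, and Krt19 by 4.87 ± 0.95 and 4.94 ± 0.95. Cdh1 was at least 52.1-fold higher than in samples 1 and 2, and differed by 0.85 ± 0.80 from samples 3 and 4 (not called). Afp differed by -0.82 ± 0.42 (not called) and -8.20 ± 0.42, and Vim fell by 2.21 ± 0.57 and rose by 3.22 ± 0.57, in that order.

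The fetal liver list fell in HB tumors for 10 of 13 (10 adjusted over the list alone, median -2.36, adjusted p = 4.1e-08, and 0.00192 with an estimated correlation). Cholangiocyte and progenitor genes rose for 12 of 19 (12 adjusted over the list alone, median 2.25, adjusted p = 0.00105, or 0.337 with an estimated correlation). Epithelial junction genes such as Krt18 (4.99 ± 0.58) and Cldn3 (4.07 ± 0.40) rose for 20 of 24 (20 adjusted over the list alone, median 2.60, 2.17 with bounds, adjusted p = 4.1e-08, or 0.337 with an estimated correlation). DNA replication genes such as Uhrf1 (1.84 ± 0.25) rose for 16 of 26 (16 adjusted over the list alone, median 1.35, adjusted p = 2.4e-07, or 0.337 with an estimated correlation). Mitosis genes rose for 9 of 17 (9 adjusted over the list alone, median 1.13, adjusted p = 6.8e-06, or 0.337 with an estimated correlation). Cholesterol synthesis genes, Dhcr7 (-3.55 ± 0.34) and Lss (-2.96 ± 0.29) among them, fell for 10 of 15 (10 adjusted over the list alone, median -1.61, adjusted p = 1.8e-07, or 0.17 with an estimated correlation). Antigen presentation genes such as Cd74 (5.92 ± 0.46) and H2-Ab1 (5.44 ± 0.53) rose for 9 of 17 (9 adjusted over the list alone, median 1.05, 0.77 with bounds, adjusted p = 9.7e-06, or 0.337 with an estimated correlation). Interferon response genes rose for 11 of 17 (11 adjusted over the list alone, median 1.66, adjusted p = 6.9e-04, or 0.502 with an estimated correlation). HB tumors 3 and 8, noted after the data were seen, lay lower than the other 18 on the cholangiocyte list (6.56 and 6.51, mean log2 level, against 7.58 to 9.07), near the parental mean of 6.25. The same held for the epithelial junction list (6.96 and 6.55, against 8.07 to 9.62, parental mean 6.32), and Krt19 was under 8 in both, against a median of 11.77 in the 18. Against each pair of HB parental samples alone, these 8 lists kept the direction given here.

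Other lists depended on which HB parental samples stood for the cells of origin. Plasma protein genes rose for 19 of 26 (19 adjusted over the list alone, median 3.30, adjusted p = 4.8e-06, or 0.508 with an estimated correlation) over all samples. Against samples 1 and 2 the list rose for 24 of 26 (26 adjusted over the list alone, median 7.32, 6.66 with bounds, adjusted p = 4.2e-21, or 0.104 with an estimated correlation). Against samples 3 and 4 only 1 of 26 was higher and 4 were lower (median -0.82, adjusted p = 0.143). Targets of p53 fell for 6 of 19 (6 adjusted over the list alone, median -0.78, adjusted p = 0.007, or 0.337 with an estimated correlation). That call was lost without HB parental sample 1 or 2 (median -0.30 and -0.47), and against samples 3 and 4 the list had median 0.03, 0.00 with bounds, adjusted p = 0.449. Endothelial markers rose for 12 of 18 (12 adjusted over the list alone, median 1.29, 1.27 with bounds, adjusted p = 0.0026, or 0.502 with an estimated correlation). Against samples 3 and 4 they had median 0.85, 0.49 with bounds, adjusted p = 0.201. Fibroblast and stellate cell markers were lower than in samples 1 and 2 for 13 of 21 (13 adjusted over the list alone, median -1.61, adjusted p = 0.00875, or 0.452 with an estimated correlation). They were higher than in samples 3 and 4 for 17 of 21 (17 adjusted over the list alone, median 2.56, 2.32 with bounds, adjusted p = 8.2e-08, or 0.221 with an estimated correlation). HB parental arrays shared no batch with HB tumors, so batch and group cannot be told apart, and with batch as a random block 1593 genes were called, without Tff1.

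In AH tumors all 22 urea cycle and amino acid genes tested fell, as did all 23 genes of drug and bile acid metabolism. Genes of division (Prc1, undetected in parental cells), matrix and fetal liver rose. Which cells carried these changes was not tested. Among the largest rises were Emp1 (at least 212-fold higher), the prolactin family gene Prl2c3 (at least 144-fold higher), Acta2 (at least 86.3-fold higher) and the protease inhibitor Timp1 (at least 84.4-fold higher). Among the largest falls were Serpina1e (-8.98 ± 0.89) and Car3 (-8.18 ± 0.80) and the cytochromes Cyp2a12 (-7.88 ± 0.65), Cyp2f2 (-7.33 ± 1.08) and Cyp4a12b (-7.26 ± 0.34). Krt19, not detected in parental hepatocytes, was at least 9.30-fold higher, and Sox9 rose by 2.77 (log2). The surface receptor Cd44 (5.30 ± 0.50) and the cell cycle inhibitors Cdkn1a (3.53 ± 0.33) and Cdkn2a (at least 15.1-fold higher) rose. Hnf4a fell by 1.67 ± 0.68, a call lost with AH tumors 1 to 10 alone (-0.53) and without any 1 of the 4 AH parental samples (-1.71 to -1.65). In limma 4446 genes were called, 2509 higher and 1937 lower.

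Urea cycle and amino acid catabolism fell in AH tumors for 22 of 22 (22 adjusted over the list alone, median -4.01, adjusted p = 4.2e-07, or 0.435 with an estimated correlation), and xenobiotic and bile acid metabolism, including Abcb11 (-6.82 ± 0.37), for 23 of 23 (23 adjusted over the list alone, median -4.19, adjusted p = 1.2e-07, or 0.414 with an estimated correlation). Gluconeogenesis and fatty acid oxidation, including the glucose transporter Slc2a2 (-6.29 ± 0.62), fell for 17 of 18 (17 adjusted over the list alone, median -3.02, adjusted p = 7.2e-06, or 0.414 with an estimated correlation). Hepatocyte transcription factors such as Cebpa (-4.26 ± 0.36) fell for 13 of 16 (13 adjusted over the list alone, adjusted p = 6.8e-04, adjusted p = 0.509 with an estimated correlation). Plasma protein genes fell for 11 of 26 (8 adjusted over the list alone, median -1.52, adjusted p = 0.0253, or 0.722 with an estimated correlation). Mitosis genes such as Prc1 (at least 68.8-fold higher) and Cdk1 (at least 22.1-fold higher) rose for 15 of 17 (15 adjusted over the list alone, median 4.79, 3.55 with bounds, adjusted p = 2.9e-14, and 0.0482 with an estimated correlation). DNA replication genes such as Uhrf1 (at least 50.0-fold higher) and Mcm2 (4.15 ± 0.23) rose for 23 of 26 (23 adjusted over the list alone, median 2.78, 2.47 with bounds, adjusted p = 5.7e-11, or 0.164 with an estimated correlation). Genes downstream of MAPK signaling, Ier3 (5.78 ± 0.24) and Hbegf (at least 12.2-fold higher) among them, rose for 12 of 18 (12 adjusted over the list alone, median 1.76, 1.29 with bounds, adjusted p = 2.5e-04, or 0.293 with an estimated correlation). Notch pathway genes such as Hey1 (3.40 ± 0.47) rose for 6 of 13 (6 adjusted over the list alone, median 0.95, 0.00 with bounds, adjusted p = 0.0278, or 0.164 with an estimated correlation). Fetal liver genes such as Igf2bp3 (at least 7.44-fold higher) and Dlk1 (at least 3.70-fold higher) rose for 10 of 13 (10 adjusted over the list alone, median 1.49, 0.49 with bounds, adjusted p = 0.0253, or 0.382 with an estimated correlation), a list call lost without background correction and with AH tumors 11 to 20 alone (median 1.03, adjusted p = 0.058). Hypoxia and glycolysis genes rose for 15 of 23 (15 adjusted over the list alone, median 1.40, 1.05 with bounds, adjusted p = 2.5e-04, or 0.414 with an estimated correlation), with the glycolytic enzyme Pkm at 7.51 ± 0.37. Cholesterol synthesis genes fell for 6 of 15 (6 adjusted over the list alone, median -0.73, adjusted p = 0.0278, or 0.534 with an estimated correlation), but not with AH tumors 1 to 10 alone (median -0.69, adjusted p = 0.0529).

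Stromal and immune markers rose in AH tumors as well. Fibroblast and stellate cell markers, Col5a1 (at least 43.5-fold higher) and Cygb (at least 22.7-fold higher) among them, rose for 20 of 21 (20 adjusted over the list alone, median 3.07, 2.49 with bounds, adjusted p = 2.2e-06, or 0.382 with an estimated correlation). Mesenchymal transition genes such as Axl (6.32 ± 0.43) rose for 18 of 22 (18 adjusted over the list alone, median 3.00, 2.23 with bounds, adjusted p = 3.3e-04, or 0.534 with an estimated correlation). Macrophage markers such as Cd14 (at least 25.4-fold higher) rose for 9 of 17 (9 adjusted over the list alone, median 1.51, 0.91 with bounds, adjusted p = 0.0305, or 0.68 with an estimated correlation). The macrophage call was lost with array weights, with AH tumors 1 to 10 alone (median 1.06, adjusted p = 0.129) and without AH parental sample 4 (median 1.14). Granulocyte markers had 8 of 12 members higher (8 adjusted over the list alone), including S100a8 (at least 10.8-fold higher), but the list test did not pass (median 1.60, 0.05 with bounds, adjusted p = 0.203), though it did with no filter. WNT targets moved both ways, with 4 higher, 6 lower and a test that did not pass (median -1.40, adjusted p = 0.556). Neither did skeletal muscle (median -0.01, 0.00 with bounds, adjusted p = 0.547), keratinocyte (median 0.70, 0.00 with bounds, adjusted p = 0.741), lymphocyte (median 0.47, 0.00 with bounds, adjusted p = 0.531) and adipocyte markers (median 0.05, -0.11 with bounds, adjusted p = 0.263). AH parental arrays formed an array batch of their own, so batch and group cannot be told apart.

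Tumors of all 3 origins shared a set of changes from their parental cells. Shared rises included Cygb, Prkg2, Rasgrf1, Klra4, Cdx2, Ifi27l2a and Pbp2, among which Cdx2 is a transcription factor of intestinal epithelium and Rasgrf1 an exchange factor that activates Ras. Cygb rose by 5.46 ± 0.32 in HPC and 4.50 ± 0.30 in HB tumors and was at least 22.7-fold higher in AH tumors. Rasgrf1 was 4.54 ± 0.52 in HPC, at least 5.24-fold higher in HB and at least 5.70-fold higher in AH tumors. Shared falls included the aminopeptidase Anpep (-2.32 ± 0.52, -3.12 ± 0.48 and -3.06 ± 0.48 for HPC, HB and AH), Zfp36, Kank1, Arhgap24 and Grb14. In all, 267 genes rose and 98 fell in all 3 lineages, where independent lists would share 44.3 and 29.3. With median centring 170 rose and 130 fell. Another 1028 genes were called in opposite directions in at least 2 lineages. Against HB parental samples 1 and 2 alone, Zfp36 was not called lower in HB tumors. Mitosis and DNA replication lists rose in each lineage with the preset correlation, and with an estimated correlation only mitosis in AH tumors passed (adjusted p = 0.0482).

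The change from parental cell to tumor differed between lineages for many genes, among them those that had separated the parental cells. Hepatocyte genes rose in HPC tumors and fell in AH tumors, and the bile duct genes Krt19 and Sox9 did the opposite. The difference between the HPC and AH changes was at least 7466-fold for Mup2 and 11.83 ± 1.59 for Cyp2f2, and on the other side Krt19 was at least 38.9-fold lower and Sox9 (-4.30 ± 0.43) lower. Plasma protein genes were higher for 22 of 26 (23 adjusted over the list alone, median 5.91, 5.86 with bounds, adjusted p = 3.3e-07, or 0.566 with an estimated correlation). Xenobiotic and bile acid genes were higher for 21 of 23 (21 adjusted over the list alone, median 8.17, 7.97 with bounds, adjusted p = 6.5e-12, or 0.308 with an estimated correlation). Cholangiocyte and progenitor genes were lower for 17 of 19 (17 adjusted over the list alone, median -6.13, -4.30 with bounds, adjusted p = 1.8e-07, or 0.148 with an estimated correlation). YAP targets were lower for 11 of 12 (11 adjusted over the list alone, median -2.61, -1.69 with bounds, adjusted p = 1.0e-04, or 0.148 with an estimated correlation). Mitosis genes were lower for 14 of 17 (14 adjusted over the list alone, median -2.32, -2.13 with bounds, adjusted p = 4.0e-07, or 0.3 with an estimated correlation). In limma 4748 genes were called, 1910 higher in the HPC change and 2838 lower, and the median over all genes was -0.21, against which these changes should be read.

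The HPC change differed from the HB change for 3218 genes (1453 higher, 1765 lower), and with median centring for 992 higher and 1947 lower. Epithelial genes fell in HPC tumors and rose in HB tumors, with Cldn4 (-11.17 ± 1.08), Krt7 (-9.59 ± 1.46) and Cdh1 (-6.74 ± 1.04). The epithelial junction list was lower for 21 of 24 (21 adjusted over the list alone, median -5.59, -5.12 with bounds, adjusted p = 5.2e-15, or 0.115 with an estimated correlation). The cholangiocyte and progenitor list was lower for 16 of 19 (16 adjusted over the list alone, median -5.69, adjusted p = 1.0e-13, and 0.00742 with an estimated correlation). Fetal liver genes such as Igf2 (at least 305-fold higher) and Cdkn1c (5.74 ± 0.69) were higher for 11 of 13 (11 adjusted over the list alone, median 2.96, adjusted p = 6.3e-08, and 0.00269 with an estimated correlation). Fibroblast and stellate cell markers were higher for 15 of 21 (15 adjusted over the list alone, median 3.25, 2.78 with bounds, adjusted p = 3.9e-05, or 0.424 with an estimated correlation), a call lost without HB samples 1 and 2 (adjusted p = 0.118). Antigen presentation genes were lower for 11 of 17 (11 adjusted over the list alone, median -1.79, -1.53 with bounds, adjusted p = 4.8e-05, or 0.424 with an estimated correlation). The HB change differed from the AH change for 4138 genes (1818 higher, 2320 lower), or 2335 with array batch as a random block. The fetal list was lower for 12 of 13 (12 adjusted over the list alone, median -4.76, -3.04 with bounds, adjusted p = 4.0e-09, and 8.9e-04 with an estimated correlation). Mitosis genes were lower for 15 of 17 (15 adjusted over the list alone, median -3.46, -2.61 with bounds, adjusted p = 4.5e-13, and 0.0368 with an estimated correlation). Plasma protein genes were higher for 23 of 26 (26 adjusted over the list alone, median 5.13, adjusted p = 5.9e-08, or 0.315 with an estimated correlation), which was lost without HB samples 1 and 2 (adjusted p = 0.113).

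The 20 AH tumors were compared as 2 sets by their numbers. The labels do not describe this grouping, which was chosen after the data were seen. The split was not clean. AH tumors 12 and 16 held Krt19 at 11.45 and 11.10 (log2), at least as high as tumors 1 to 10 (9.68 to 10.90). The rest of 11 to 20 lay at 6.58 to 9.14. In limma 782 genes were called between AH tumors 1 to 10 and 11 to 20, 521 higher in tumors 1 to 10 and 261 lower. Within array batch 1, tumors 7 to 10 differed from 11 to 20 in 573 genes, and within tumors 1 to 10 the batches (1 to 6 against 7 to 10) differed in 148. Interferon response genes were lower in tumors 1 to 10 (median -1.50, adjusted p = 3.0e-10, or 0.332 with an estimated correlation), at a mean log2 level of 7.42 against 8.87. Antigen presentation (median -1.37, adjusted p = 3.0e-07, or 0.412 with an estimated correlation) and macrophage markers (median -0.76, adjusted p = 0.0132, or 0.936 with an estimated correlation) were lower too. Most of the macrophage difference lay in tumors 7 to 10 (mean log2 level 7.33, against 8.25 in tumors 1 to 6 and 8.56 in 11 to 20). Also lower were fibroblast and stellate cell markers (median -0.61, adjusted p = 0.00803, or 0.862 with an estimated correlation), and epithelial junction (median 0.95, adjusted p = 3.2e-08, or 0.154 with an estimated correlation), cholangiocyte (median 0.93, adjusted p = 1.1e-04, or 0.069 with an estimated correlation) and hypoxia and glycolysis genes (median 0.29, adjusted p = 0.031, or 0.936 with an estimated correlation) were higher. Each result that used AH tumors was an average over these sets.

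Between tumors of different origin the differences were smaller than between tumors and parental cells. HPC tumors exceeded AH tumors in liver products, antigen presentation, interferon and macrophage genes and were lower in MAPK output. Highest in HPC tumors were Trappc8 (5.23 ± 0.19) and the liver proteins Mup21 (4.08 ± 0.73), Mup2 (3.55 ± 0.79) and Car3 (3.47 ± 0.56). Among the lowest were the prolactin family gene Prl2c4 (-6.31 ± 0.45), the keratin Krt20 (-4.94 ± 0.59), the natriuretic peptide Nppb (-4.21 ± 0.45) and the transcription factor Tfap2a (-3.95 ± 0.34). Antigen presentation genes such as Psmb9 (1.66 ± 0.27), under 2-fold with median centring, were higher for 13 of 17 (13 adjusted over the list alone, median 1.19, adjusted p = 3.9e-10, or 0.344 with an estimated correlation). In array batch 1 alone the list had median 1.03, adjusted p = 1.1e-07. Interferon response genes such as Ifit3 (2.40 ± 0.46) and Oasl2 (2.04 ± 0.37) were higher for 9 of 17 (9 adjusted over the list alone, median 1.19, adjusted p = 5.6e-08, or 0.344 with an estimated correlation), with median 0.94, adjusted p = 6.9e-05 in batch 1. Macrophage markers such as Adgre1 (1.88 ± 0.29) and the Kupffer cell gene Clec4f (2.45 ± 0.46) were higher for 10 of 17 (10 adjusted over the list alone, median 1.03, adjusted p = 9.4e-05, or 0.521 with an estimated correlation), with median 1.02, adjusted p = 6.9e-05 in batch 1. With AH tumors 11 to 20 alone the 3 lists had median 0.59, adjusted p = 0.00109, median 0.45, adjusted p = 0.0378 and median 0.60, adjusted p = 0.00805, in that order, and Psmb9 (0.94) and Ifit3 (0.81) were not called. With AH tumors 1 to 10 alone the medians were 1.84, 1.98 and 1.40. In limma 749 genes were called, 411 higher and 338 lower, and 890 in batch 1 alone, the only batch with both groups. With median centring in place of quantile normalization, 96 higher and 1352 lower were called and the median of all genes was -0.40, and without background correction 188 higher and 98 lower.

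Xenobiotic and bile acid genes were higher in HPC than AH tumors for 11 of 23 (12 adjusted over the list alone, median 1.63, adjusted p = 9.4e-05, or 0.671 with an estimated correlation). Urea cycle and amino acid genes were higher for 6 of 22 (6 adjusted over the list alone, median 0.99, adjusted p = 0.00702, or 0.81 with an estimated correlation). Plasma protein genes were higher for 5 of 26 (2 adjusted over the list alone, median 1.01, adjusted p = 0.00212, or 0.81 with an estimated correlation). Medians in batch 1 alone were 1.68, 1.40 and 1.49, in that order. MAPK output genes such as Phlda1 (-1.22 ± 0.18) were lower for 5 of 18 (5 adjusted over the list alone, median -0.57, adjusted p = 9.4e-05, or 0.344 with an estimated correlation), with median -0.60, adjusted p = 6.9e-05 in batch 1. No member of the mitosis list (median -0.43, -0.30 with bounds, adjusted p = 0.00517, or 0.642 with an estimated correlation) or of the MYC and ribosome biogenesis list (median -0.35, -0.32 with bounds, adjusted p = 9.2e-04, or 0.344 with an estimated correlation) was called, though both lists were lower as sets. In batch 1 alone they had median -0.36, adjusted p = 0.00319 and median -0.38, adjusted p = 0.00246. With AH tumors 1 to 10 alone the urea cycle list did not pass (median 0.59, adjusted p = 0.0936). Krt19, Sox9, Cdh1 and Vim were not called between HPC and AH tumors, though against AH tumors 1 to 10 alone Krt19 (-1.43) and Cdh1 (-1.58) were called lower.

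HB tumors exceeded both other tumor groups in gastrokines, secreted proteins of the stomach lining, and in epithelial junction genes. Tumors 3 and 8 were exceptions, without detected Gkn1 or Gkn2 and with the epithelial levels given above. Gkn1 was not detected in HB tumor 11 either, nor Gkn2 in tumors 6 and 11. HPC tumors were lower than HB tumors in the keratin Krt20 (-6.91 ± 0.59), in Tff1, in the gastrokines Gkn2 (at least 35.7-fold lower) and Gkn1 (at least 29.7-fold lower) and in Prap1 (-6.85 ± 0.82). They were higher in Trappc8 (5.58 ± 0.19), the growth factor Ptn (3.64 ± 0.54) and the endothelial gene Esm1 (3.57 ± 0.37). Tff1 differed by -6.75 ± 1.04, and by -4.30 (not called) with array batch as a fixed factor. HPC and HB tumors shared no array batch, and that factor linked them only through AH tumors 1 to 6 and 7 to 20, which also differed by set. Epithelial junction genes such as St14 (-3.07 ± 0.36) were lower for 16 of 24 (16 adjusted over the list alone, median -1.94, -1.66 with bounds, adjusted p = 1.9e-09, or 0.417 with an estimated correlation), with median -1.43, adjusted p = 4.5e-06 in that fit. Cdh1 and Krt7 were -2.23 ± 0.50 and -3.37 ± 0.70, and in that fit -0.64 and -1.16, neither called. In limma 1277 genes were called, 594 higher and 683 lower, and 1059 with the batch factor. With median centring 71 higher and 2826 lower were called and the median of all genes was -0.57.

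Macrophage markers such as C1qa (2.03 ± 0.30) were higher in HPC than HB tumors for 9 of 17 (9 adjusted over the list alone, median 1.01, adjusted p = 0.00115, or 0.732 with an estimated correlation), with median 0.89, adjusted p = 0.00286 in that fit. Antigen presentation genes were higher for 12 of 17 (12 adjusted over the list alone, median 1.25, adjusted p = 2.5e-06, or 0.417 with an estimated correlation), with median 0.54, adjusted p = 0.0267 in that fit. Interferon response genes were higher for 8 of 17 (8 adjusted over the list alone, median 0.96, adjusted p = 0.00223, or 0.732 with an estimated correlation). With the batch factor that call was lost (median -0.08, adjusted p = 0.929). Fibroblast and stellate cell markers such as Lrat (2.92 ± 0.35) were higher for 9 of 21 (9 adjusted over the list alone, median 0.83, adjusted p = 0.00162, or 0.732 with an estimated correlation), with median 0.56, adjusted p = 0.033 in that fit. Fetal genes, with Igf2bp1 (-3.27 ± 0.25) and Igf2bp3 (-2.07 ± 0.18), were lower for 4 of 13 (4 adjusted over the list alone, median -0.78, adjusted p = 0.00469, or 0.417 with an estimated correlation). That list call was lost with median centring and with the batch factor (median -0.65, adjusted p = 0.0696).

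Against AH tumors, HB tumors were again higher in Prap1 (5.64 ± 0.67), Gkn2 (5.46 ± 0.68) and Gkn1 (5.18 ± 0.59), the mucus cell genes Clca1 (4.84 ± 0.45) and Tff3 (4.65 ± 0.61) and Ckmt1 (4.01 ± 0.64). They were lower in Rbfox1 (-2.94 ± 0.31) and Calb2 (-2.64 ± 0.35), the kinase Lrrk2 (-2.42 ± 0.27) and the signal protein Wnt5a (-2.25 ± 0.42). Epithelial junction genes such as Rab25 (3.23 ± 0.33) and St14 (2.58 ± 0.30) were higher for 13 of 24 (13 adjusted over the list alone, median 1.59, adjusted p = 2.7e-15, or 0.322 with an estimated correlation). In array batch 3 alone the list had median 1.48, adjusted p = 2.4e-16. Cholangiocyte and progenitor genes were higher for 8 of 19 (8 adjusted over the list alone, median 0.75, adjusted p = 0.00232, or 0.39 with an estimated correlation), with median 0.62, adjusted p = 0.0213 in batch 3, and did not pass with array batch as a fixed factor (median 0.62, adjusted p = 0.0547) or with median centring. Mesenchymal genes were lower for 6 of 22 (6 adjusted over the list alone, median -0.52, adjusted p = 0.0155, or 0.878 with an estimated correlation), with median -0.52, adjusted p = 0.00666 in batch 3. MAPK output genes were lower for 3 of 18 (3 adjusted over the list alone, median -0.39, adjusted p = 0.00522, or 0.39 with an estimated correlation), with median -0.49, adjusted p = 0.00182 in batch 3. Krt7, Cdh1 and Hnf4a were 2.70 ± 0.57, 1.89 ± 0.41 and 1.46 ± 0.39, and in batch 3 alone 1.33, 0.94 and 0.46, none called there. In limma 541 genes were called, 369 higher and 172 lower, 447 in batch 3 alone and 1134 with AH tumors 11 to 20 alone. With median centring the split was 546 higher and 88 lower. Of AH tumors, batch 3 held only 1 to 6. With AH tumors 1 to 10 alone the cholangiocyte list (median 0.16, adjusted p = 0.176), Krt7 (0.67), Cdh1 (0.65) and Hnf4a (0.32) were not called. With AH tumors 11 to 20 alone the mesenchymal (median -0.69, adjusted p = 0.077) and MAPK lists (median -0.43, adjusted p = 0.077) did not pass.

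Other list calls between HB and AH tumors were lost within array batch 3, which held fewer arrays. Adipocyte markers such as Pparg (1.59 ± 0.32) were higher for 2 of 8 (2 adjusted over the list alone, median 0.35, adjusted p = 0.0346, or 0.39 with an estimated correlation), with median 0.44, adjusted p = 0.0618 in batch 3. That call was also lost without HB tumors 3 and 8 (median 0.33, adjusted p = 0.0514) and without AH tumor 2 or 13 (median 0.32 each). Fibroblast and stellate cell markers were lower for 2 of 21 (3 adjusted over the list alone, median -0.59, adjusted p = 0.0156, or 0.878 with an estimated correlation), with median -0.25, adjusted p = 0.228 in batch 3. With AH tumors 1 to 10 alone neither list passed.

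**Figure D5:**
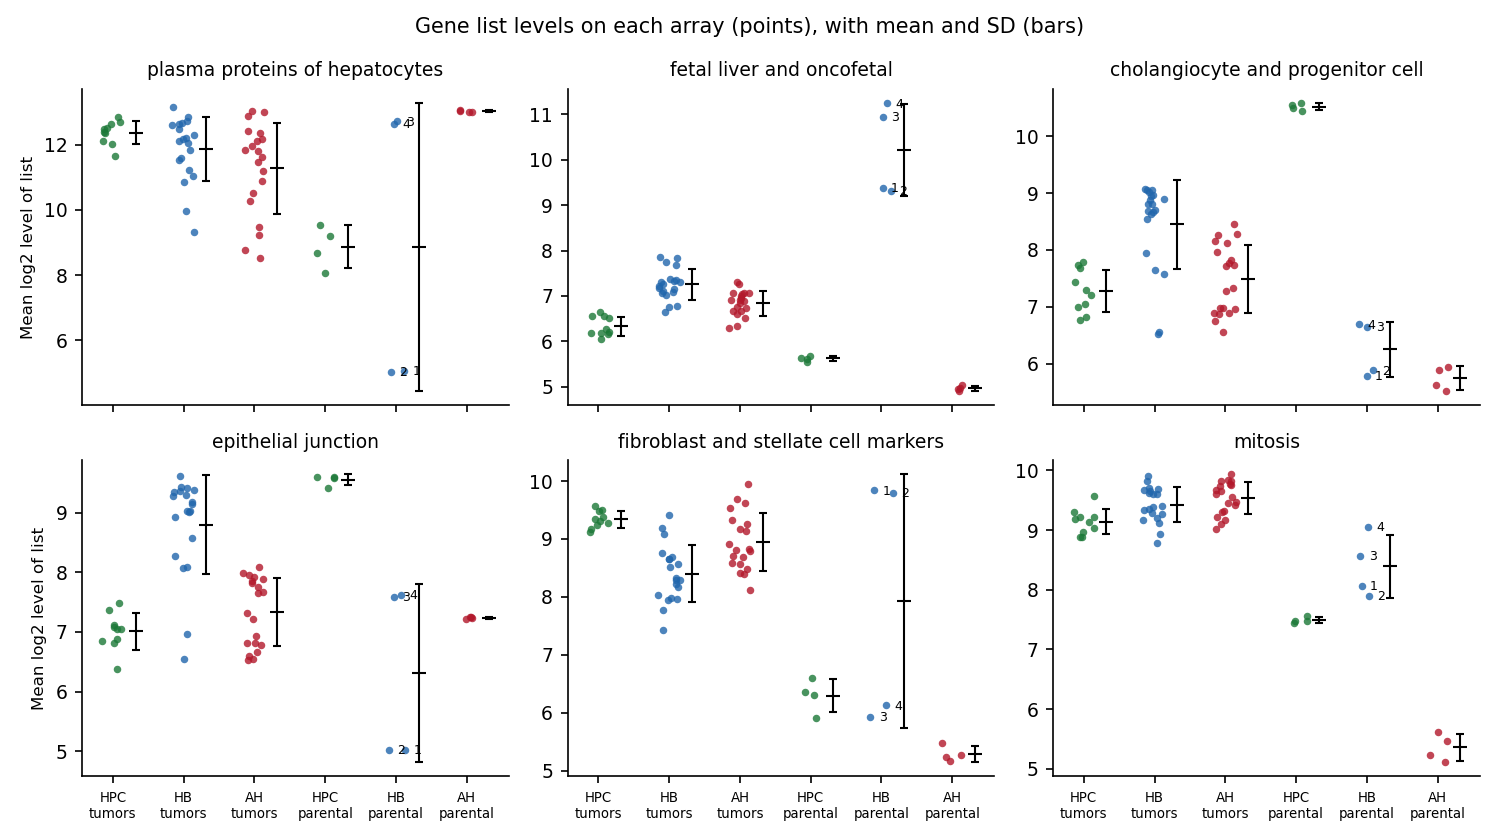
Points show the mean log2 level of 6 gene lists on each array by group, with the group mean and SD beside them and HB parental samples numbered. The cholangiocyte and progenitor list averages 10.52 ± 0.06 in HPC parental cells, 8.45 ± 0.79 in HB tumors and 5.75 ± 0.20 in AH parental cells, and mitosis averages 5.36 ± 0.23 in AH parental cells.

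The differences that separated the parental cells mostly did not persist in the tumors. Across genes, which are not independent replicates, the HPC against AH differences of parental cells and of tumors correlated at r = -0.246. For HPC against HB r was -0.117, and for HB against AH -0.234, but -0.0454 and -0.0488 without HB parental samples 1 and 2. With median centring the HPC against HB r was -0.0322, and with the plasma protein level as a covariate the HB against AH r was -0.0616. With tumors of array batch 1 alone (parental cells in batches 1 and 6) the HPC against AH r was -0.287. Among the genes called between HPC and AH parental cells, 41.5% kept their sign in tumors. Genes called in both comparisons numbered 132 with the same sign, against 149 for independent lists, and 266 with opposite signs, against 144. For HPC against HB 189 kept their sign, more than the 129.9 for independent lists, and 260 were opposite, against 135. For HB against AH 47 kept their sign, against 75.6, and those of opposite sign again exceeded the 70.8 for independent lists. Corrected for error, tumors of 2 origins lay closer than their parental cells, at 0.296 times the parental distance for HPC and AH, 0.65 for HPC and HB (0.478 to 0.872 over the alternatives) and 0.339 for HB and AH (0.231 to 0.471 over the alternatives). The HPC and AH ratio was 0.307 with tumors of batch 1 alone. With the plasma protein level of each tumor as a covariate, a test chosen after the data were seen, the HPC against AH r became 0.0349.

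HPC tumors were the most uniform. Their mean distance from the group mean was 0.402 ± 0.074 (SD, n = 10), against 0.614 ± 0.0913 in AH tumors (n = 20) and 0.564 ± 0.162 in HB tumors (n = 20). The 2-sided permutation test gave p = 1.0e-05 for HPC against AH (the smallest that 100000 resamples can give, adjusted p = 3.0e-05 over 3 tests). It gave p = 0.0053 for HPC against HB (adjusted p = 0.00795) and p = 0.23 for HB against AH (adjusted p = 0.23). HPC tumors all lay in array batch 1, and against the AH tumors of that batch the difference was -0.193 (permutation test, adjusted p = 3.0e-04). That batch held both AH sets, and the distance from 1 AH mean included the difference between them. Against tumors 11 to 20 or 1 to 10 alone it was -0.143 (adjusted p = 0.00153) and -0.149 (adjusted p = 0.00844). HB and HPC tumors shared no batch, and the noise of probes almost never detected (MAD, log2) was 0.0553 to 0.0706 in batch 1 and 0.0957 to 0.127 in batches 2 and 3, which can widen the HB distances. Without HB tumors 3 and 8 the adjusted p was 0.0359 for HPC against HB and for HB against AH (difference -0.0898). The plasma protein list ranged over 8.53 to 13.03 among AH tumors and 11.65 to 12.85 among HPC tumors.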

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

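The tests for blood-forming and mesenchymal cells, for host liver RNA and of the array batch of parental cells, the array batches themselves and the sets of AH tumors were chosen after the results were seen.

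HB parental samples 1 and 2 differed from samples 3 and 4 in 3521 genes and lay in separate array batches. Array batch as hybridization noise of single probes is argued against by the 2 brightest probes of the same genes, whose differences between the pairs correlated at r = 0.887 over 2848 pairs of probes. Blood-forming cells in samples 3 and 4 as the whole cause are argued against by the plasma protein list, which was higher there by a median of 8.25 (log2). Mesenchymal cells in samples 1 and 2 stay open: the 100 genes outside all lists that followed the fibroblast list across tumors were higher there by a median of 2.92 (quartiles 0.90 and 4.93), 89% of them higher, against 0.02 for all genes. A difference in the cells or their culture between the pairs, which the labels do not describe, may also contribute and was not tested.

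Hepatocyte plasma protein genes were higher in HPC tumors than in HPC parental cells, both in array batch 1. RNA of host liver in the tumors stays open. The median difference from AH parental cells was -3.07 (quartiles -3.89 and -2.35) for 76 genes bright there and undetected in HPC parental cells. Of them 86.8% lay within 2 (log2), too wide a window to test 1 common difference (SD 1.27). Abcb11 (-6.86), Cyp4a12b (-6.66) and F10 (-0.34) lay outside. The plasma list averaged 12.38 in HPC tumors and 13.04 in AH parental cells. That argues against host RNA at -3.07 as the whole cause of its rise. Hepatocyte genes turned on in tumor cells remain possible beside host tissue and were not told apart.

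The HPC against AH differences of parental cells mostly did not persist in tumors (r = -0.246 across genes). Array batch of the tumors is argued against by r = -0.287 with tumors of batch 1 alone. The parental cells lay in batches 1 and 6, and batch as hybridization noise of single probes is argued against there by r = 0.895 between the parental differences of the 2 brightest probes, while what batch could add otherwise stays open. Hepatocyte RNA that differs between tumors stays open for the negative sign alone: with the plasma protein level of each tumor as a covariate r was 0.0349, so the differences of parental cells did not carry over to the tumors with or without it. A loss of lineage differences in the transformed cells stays among the open explanations, as does their replacement by cells of other types.

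Splits of the same samples were counted for 13 results, 100 each with the real one, or all 35 for parental comparisons. In each of the 13, 1 split gave a count as large, the real one, which argues against a random grouping of the samples. The real counts and the highest of the other splits were 2925 and 1334 for HPC, 2401 and 821 for HB and 4446 and 1519 for AH tumors against parental cells. Between tumors they were 749 and 160 for HPC and AH, 1277 and 628 for HPC and HB, and 541 and 15 for HB and AH. Between parental cells they were 4041 and 0, 2142 and 0, and 2792 and 5, in the same order, and the genes shared by all lineages numbered 365 and 0. Between HB and AH tumors batch 3 alone gave 447 genes, and AH tumors 11 to 20 alone 1134.

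The tumor against parental change differed between lineages by an interaction test in limma for 4748 genes (HPC against AH), 3218 (HPC against HB) and 4138 (HB against AH). The highest of 99 other splits gave 4050, 2391 and 2061, and in the first of these splits the parental groups stayed whole and only tumors changed places. These counts therefore carry the differences between parental cells. Of 1719 probes without a listed gene, 340 were detected on every array, above the negative control probes.

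A distant sample was sought in each of the 4 groups of 10 or fewer, for the level of each of 30 lists and for probes detected, and for the distance of HPC tumors from their mean. Of these, 12 values lay apart where chance gives about 1 in 20 tests. HPC tumor 4 was lowest for gluconeogenesis and fatty acid oxidation (7.84, mean log2 level) and HPC tumor 3 lowest for the Notch list (6.35). HPC parental sample 1 was lowest for gluconeogenesis and fatty acid oxidation (7.17) and hepatocyte transcription factors (7.95) and highest for granulocyte markers (6.38). HPC parental sample 2 was lowest for DNA replication (7.51) and for MYC and ribosome biogenesis (9.23). HPC parental sample 4 was lowest for epithelial junction (9.41) and highest for skeletal muscle (5.94). AH parental sample 4 was highest for cholesterol synthesis (10.14) and lowest for antigen presentation (7.51), and AH parental sample 3 highest for lymphocyte markers (5.22).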

How the results depend on the processing

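Alternatives that use array batch, leave out sets of samples or add the plasma protein level were chosen after the results were seen. With the series matrix values (for example 3060 genes for HPC tumors against parental cells) or the replicate number as a block (2787), counts stayed within 1.5-fold. The same held with no filter, detection on at least 10 arrays, all probes, the mean of the probes of a gene, a trended and robust prior, and only the compared groups or all 6 in the fit, where each could be run. With the distance as 1 minus Pearson r, the 3 comparisons of tumor spread kept direction and side of the threshold. The slide term was not run, since the files name no slides. Over all alternatives, 1250 list values kept direction and side of the threshold, 155 weakened, 8 strengthened and 5 reversed, and for genes 11009, 379, 153 and 29. Of the 155, 98 were list calls lost with an estimated correlation, which left 15 the same. Signal over background limits dim genes.

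Without background correction, 1566, 1237 and 2689 genes were called for tumors against parental cells in HPC, HB and AH. Between tumors the counts were 286 (HPC and AH), 523 (HPC and HB) and 221 (HB and AH), and between parental cells 2513, 1144 and 1645 in that order. Interactions gave 2992, 1940 and 2496, 151 genes were shared, and the cause was not tested. With no minimum fold, a looser threshold by construction, tumors against parental cells gave 4903, 4649 and 6757, tumors 3330, 4655 and 3520, and 936 genes were shared.

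With median centring, 1448 genes were called between HPC and AH tumors and 2897 between HPC and HB tumors. The distance ratios were then 0.356 and 0.872, and the HPC against HB correlation -0.0322. With the mean of the probes of a gene, Cd44 differed by -1.08 between HPC and HB tumors. With array weights, 3390 genes were called between HPC and HB parental cells. For HB tumors against parental cells the plasma list then had median 0.0259, p53 targets -0.16, Cdkn1a 1.03 and Hba-a1 -0.84. Hnf4a was -1.20 for HPC against HB parental cells. Cdkn1a was -0.0383 for the HPC against HB change and Cdkn2a 0.19 for the HB against AH change. No cause was tested here.

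With array batch as a random block the counts were 1593 for HB tumors against parental cells, 2335 for the HB against AH change, and 1238, 368 and 664 between parental cells. Alb, read by the dim probe described above, was 0.67 for HPC against HB and -0.0339 for HB against AH tumors. With batch as a fixed factor these were 1.19 and -0.41 (also -0.41 in batch 3 alone), and for HPC against HB tumors the interferon list had median -0.0762 and Gbp2 -0.32. With the plasma protein level as a covariate, the correlations were 0.0349 for HPC against AH and -0.0616 for HB against AH. Without AH tumors 1 to 10, 1134 genes were called between HB and AH tumors, their distance ratio was 0.471 and Ccl5 was -0.0815 between HPC and AH tumors. Without AH tumors 11 to 20 the HPC and AH distance ratio was 0.359. Without HB tumors 3 and 8 the spread differed by -0.0898 between HB and AH tumors (adjusted p = 0.0359). The cause was not tested.

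Without HB parental samples 1 and 2, 3558 genes were called between HPC and HB parental cells, the HPC and HB distance ratio was 0.482 and the correlations were -0.0454 (HPC against HB) and -0.0488 (HB against AH). For HB tumors against parental cells the plasma list had median -0.82, p53 targets 0.0266, Cdkn1a 1.27, Trf -0.14, Zmat3 0.0569 and Hba-a1 -1.25. Hnf4a was -1.58 for HPC against HB parental cells, and Alb 1.07 and Cdh1 1.00 for HB against AH parental cells. Cdkn1a was -0.28 and Cdkn2a -0.58 for the HPC against HB change, and Cdkn2a 0.76 for the HB against AH change. Without samples 3 and 4 the counts were 3522 and 4549 for HB against HPC and AH parental cells and the ratios 0.478 (HPC and HB) and 0.231 (HB and AH). For HB tumors Vim was -2.21, Cd44 -2.06, Cdkn2a -0.38, Slc2a2 1.27 and Amy2a5 0.41, and Cd44 was 0.92 for the HPC against HB change. The cause was not tested.

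Leaving out each sample in turn moved no count or spread past these limits. For ratios and correlations the limit, the jackknife standard error, is made from these same runs. A single run can hardly pass it, so only their ranges are informative. Counts ran from 2754 to 2941, 2283 to 2659 and 4396 to 4482 for HPC, HB and AH tumors against parental cells, 698 to 806, 1231 to 1347 and 500 to 600 between tumors and 3787 to 3888, 1794 to 2462 and 2441 to 3545 between parental cells. Ratios ran from 0.288 to 0.306, 0.637 to 0.671 and 0.306 to 0.384. Of list values 2635 kept their call, 43 weakened and 12 strengthened, and 19061 gene values kept theirs, with none reversed. The changes fell on 8 list and 29 gene results that weakened and 1 and 16 that strengthened in at least 1 run.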

Other observations

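The genes described here, and the test for both sexes, were chosen after the values were seen. Cdx2, a regulator of intestinal epithelium, was detected on every tumor array, at mean log2 levels of 7.68 in HPC, 9.50 in HB and 9.36 in AH tumors. In parental cells it stood at 4.53, 5.17 and 4.68 and was detected on 1 of 12 arrays. Trappc8, which encodes part of a vesicle tethering complex, was at 11.09 in HPC tumors, against 5.52 in HB tumors, 5.86 in AH tumors and 6.71 in HPC parental cells.

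Xist, the RNA that silences 1 X chromosome in female cells, was detected on 4 of 4 HB parental arrays and 18 of 20 HB tumors, and on 0 HPC or AH arrays. Eif2s3y, a gene of the Y chromosome, was detected on 10 of 10 HPC tumors, 20 of 20 AH tumors, 14 of 20 HB tumors and 4 of 4 arrays of each parental group. Cells of both sexes in the HB samples are a candidate explanation, and Eif2s3y on 4 of 4 HB parental arrays is a test of that on the data that raised it.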
